A study of Mus musculus with 8 samples.

How the data were processed

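Sono-seq libraries were made from the hippocampus of 8 mice, 4 taken 30 min after contextual fear conditioning and 4 handled controls. Per the labels' protocols, tissue was fixed in 2% paraformaldehyde for 10 min, 1 µg of sonicated chromatin was used without immunoprecipitation, and fragments of about 300 bp were cut from a gel. Per the submitters' processing notes, Bowtie2 was used (no version named) and the genome build was mm9. The peak caller, the counting tool, and any filter on duplicate or multiply mapped reads are not given in the sources used here. Reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only. High-copy sequence can collect multiply mapped reads, and no input library was used here to set against it.

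The deposited files were 2 tables of the whole series and 8 peak lists, 1 per sample. The first table held raw read counts for 11304 regions in 8 columns, as deposited by the authors without normalisation; its lowest count was 3, and 0 columns were left unused. The second table listed the same regions in the same order with a mean z score and a number of carriers from 4 to 8, per the file headers. The peak lists held 1 z score per peak, the authors' own value, whose scaling is not stated and whose lowest value was 5 in every list. Peaks had been listed per sample, not on pooled samples. The deposited number of carriers equalled the number of samples with an overlapping peak at z of at least 30 in all 11304 regions, so the region list itself depends on how many strong peaks each library gave, and 9151 regions had more conditioned than control carriers. Between 75.1% and 81.3% of listed peaks had equal start and end, so positions were read as the starts of 50 bp steps, and 50 bp were added to each peak for covered length and Jaccard index. Coordinates are printed as deposited, and a start may differ by 1 from that in a genome browser.

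Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, group as the only term, TMM factors, two-sided, Benjamini-Hochberg adjusted p below 0.05). The filterByExpr filter (minimum count 10, minimum total 15) removed 0 regions. TMM factors were 0.332, 1.46, 0.509 and 1.03 in control replicates 1 to 4 and 1.07, 1.20, 1.54 and 2.01 in conditioned replicates 1 to 4. Since the 50 highest regions hold most of each total, CPM values with these factors compare a region with the bulk of regions, not with all reads. The common dispersion was 0.281. The SE of a log2 fold change was taken as its size over the square root of the F statistic. The edgeR test was tested on simulated data, with counts for all 11304 regions drawn from the means, dispersions and library sizes of these samples and 200 regions changed. Of 62 calls in the simulation 2 were false, and a simulation with no change gave 1 call.

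Library measures (9 in all) were compared by exact permutation of the group labels over 70 arrangements, and overlaps by exact counts over the 35 splits of 8 libraries into 4 and 4. Peaks were intersected with bedtools 2.31.1 at a minimum of 1 bp, with tables handled in Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The regions named were fixed by a rule written before the data were examined. It takes the regions past the threshold with non-overlapping groups and the largest fold, or, where fewer than 5 pass in a direction, the 10 with the smallest p in that direction, said not to pass. The alternatives also written before the data were examined were DESeq2's size factors, upper-quartile factors, region totals alone, other count filters, DESeq2 1.42.0 (Wald test), robust dispersion, limma 3.58.1 (voom), an adjusted p of 0.1, a replicate block, a loess offset over abundance, 1 or 2 factors of unwanted variation, a surrogate variable from sva 3.50.0, each sample left out in turn (for the region test and the number of peaks), stricter peaks and other overlap rules. Added after seeing the data were 3 factors of unwanted variation, fits without the 50 highest regions and with each of the 6 pairs of controls, the z minimum of 30, each sample left out in turn for exclusive regions and peak overlap, and the share of counts outside the highest regions.

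No mm9 genome or annotation was used here. The gene table at hand belongs to GRCm38.p6, and 88 deposited regions end beyond its last gene on their chromosome, which is another build. Gene names, promoter, exon and intron classes, GC content and the 18 gene lists written beforehand were therefore not analysed here, and regions are named by chromosome, start and end on mm9. Sex chromosomes were not analysed here, since the region list covers autosomes.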

Results

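Open chromatin of the mouse hippocampus was profiled by Sono-seq, in which crosslinked chromatin is sonicated and sequenced without an antibody, so that reads gather where chromatin breaks easily. The 8 libraries came from 8 adult male C57BL/6J mice of 2 months of age. In the conditioned group of 4 mice, the hippocampus was taken 30 min after contextual fear conditioning, a single training session that pairs a chamber with a foot shock (2 s, 1.5 mA). The control group of 4 mice was handled for 3 days like the trained mice, was not conditioned, and was dissected at the same time of day. Separate mice tested 24 h after training froze for 55 ± 10% of the time, with the kind of error not stated in the labels. The deposited count table held 11304 regions on 19 autosomes with a median span of 858 bp (400 to 5950 bp). Total counts over these regions were 66135693, 63478445, 36786183 and 57580689 in control replicates 1 to 4 and 75954453, 36857885, 75230707 and 83233550 in conditioned replicates 1 to 4. Because the labels describe separate animals, p-values here measure the spread between animals together with that of library preparation.

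A small set of regions took up most of the reads in all 8 libraries. The 50 regions with the most counts held 82.4% to 96.6% of a library's counts, and 22 of these 50 lay on chromosome 9 between positions 3000235 and 3038336 (mm9). The highest region, on chromosome 2 (98505835 to 98507726), held 38.9% ± 1.53 of the counts in control and 36.6% ± 1.07 in conditioned libraries (SD, n = 4 each; exact permutation p = 0.0857, Benjamini-Hochberg value 0.386 over 9 library measures). The region on chromosome 12 at 3109704 to 3110363 followed with 8.36% ± 0.461 and 7.88% ± 0.265 (SD, n = 4 each). The remaining 11254 regions shared 3.36%, 12.9%, 5.36% and 9.86% of the counts in control replicates 1 to 4 and 9.24%, 12.2%, 13.4% and 17.6% in conditioned replicates 1 to 4. Their 95% Clopper-Pearson intervals, which cover counting error only, reached at most 0.0105 percentage points to either side. The mean share was 13.1% ± 3.46 in conditioned and 7.87% ± 4.31 in control libraries (SD, n = 4 each), a difference of 5.24 points (SE 2.77; exact permutation p = 0.171, two-sided; Benjamini-Hochberg value 0.386). Outside the 50 highest regions the libraries therefore rested on 1971407 to 14639011 counts, and the median count of a region ranged from 115 in control replicate 3 to 1069 in conditioned replicate 4.

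**Figure D1:**
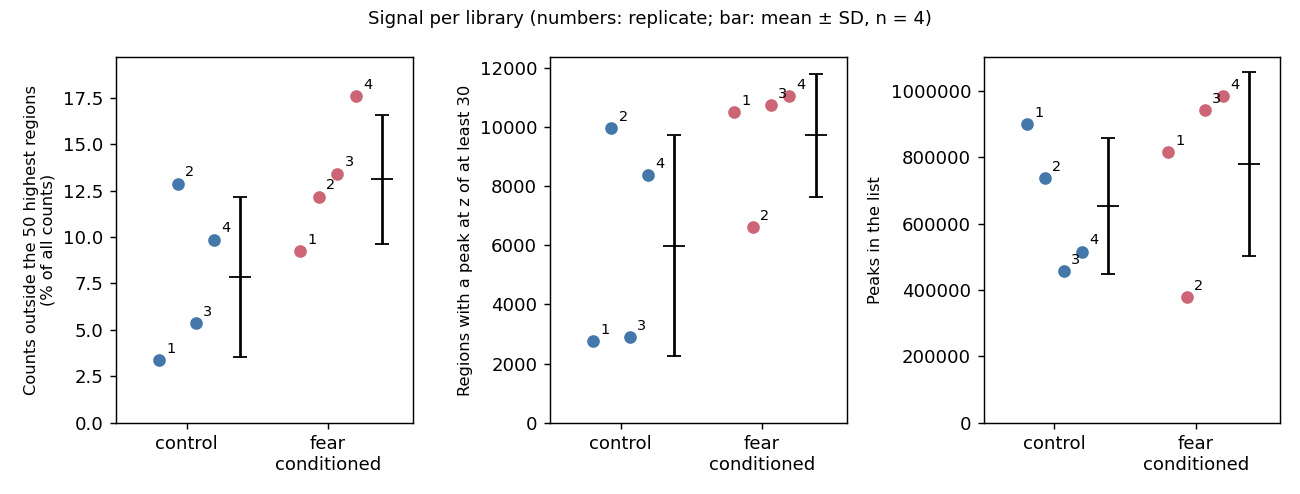
Each point is 1 library, numbered by its replicate, with the mean and SD of the 4 libraries of a group at the right of the points. The panels show the percent of counts outside the 50 highest regions, the number of regions with a peak at z of at least 30, and the number of peaks in the library's list; control replicates 1 and 3 lie lowest in the first panel, at 3.36% and 5.36%.

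The main comparison asked which regions differed in accessibility 30 min after training. No region passed the test, and the regions with the smallest p in each direction are given here by their values. On chromosome 7 at 80483713 to 80484763, conditioned libraries had 1.40 ± 0.311 and control libraries 9.10 ± 5.23 normalised read counts (CPM, TMM-scaled; SD, n = 4 each), a log2 fold change of -2.70 (SE 0.53). On chromosome 15 at 102767355 to 102767919, the means were 11.6 ± 11.4 in conditioned and 1.64 ± 0.871 CPM in control libraries (SD, n = 4 each), a log2 fold change of 2.79 (SE 0.68). The 10 regions with the smallest p in each direction had log2 fold changes from 1.38 to 2.79 on the higher side and from -3.62 to -1.97 on the lower side. They were picked for small p on these same libraries, so large folds and groups that do not overlap follow largely from the selection.

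On the higher side, the region on chromosome 14 at 35032880 to 35033377 had 10.2 ± 7.98 CPM in conditioned and 2.13 ± 0.488 CPM in control libraries (log2 fold change 2.27). The region on chromosome 17 at 47547157 to 47547710 had 11.7 ± 2.54 against 3.95 ± 1.46 CPM (log2 fold change 1.56). A second region of chromosome 14, at 56380677 to 56381680, had 21.3 ± 9.08 against 8.16 ± 1.44 CPM (1.38). Values of 20.02 ± 16.01 against 5.96 ± 2.53 CPM were found on chromosome 9 at 66197685 to 66198885 (1.74), and of 10.9 ± 4.30 against 3.37 ± 1.61 CPM on chromosome 11 at 97141331 to 97141838 (1.69). The region of chromosome 10 at 80958629 to 80959267 had 16.3 ± 11.0 against 5.63 ± 1.32 CPM (1.52), and that of chromosome 5 at 52956885 to 52957785 had 5.79 ± 1.79 against 1.88 ± 0.683 CPM (1.61). In the regions of chromosome 8 at 125393989 to 125394730 (6.52 ± 4.82 against 1.32 ± 0.883 CPM, 2.32) and chromosome 7 at 117773813 to 117774296 (5.80 ± 4.53 against 1.45 ± 0.498 CPM, 2.00), the values of the groups overlapped; in the other 8 they did not. Conditioned replicate 2 was the highest conditioned library in 9 of these 10 regions. Without it the median log2 fold change of the 10 went from 1.72 to 1.46. Without that library the estimates were 1.86 on chromosome 15, 1.6 on chromosome 14 at 35032880, 1.01 on chromosome 9 and 0.94 on chromosome 10.

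On the lower side, the groups did not overlap in any of the 10 regions, which were picked for small p on these same libraries. Their median log2 fold change was -2.23, and -2.19 against control replicates 2 and 4 alone. Conditioned replicate 2 was the lowest conditioned library in 7 of them. The region with the most reads, on chromosome 11 at 3058579 to 3060282, had 12.4 ± 4.34 CPM in conditioned and 54.2 ± 37.6 CPM in control libraries (log2 fold change -2.12, and -1.21 against control replicates 2 and 4 alone). On chromosome 2 at 100086371 to 100087171 the means were 1.68 ± 0.592 and 9.73 ± 4.41 CPM (-2.53), on chromosome 13 at 93951669 to 93952516 they were 1.27 ± 0.448 and 6.81 ± 3.60 CPM (-2.42), and on chromosome 17 at 3080449 to 3081067 they were 1.43 ± 0.211 and 7.06 ± 3.64 CPM (-2.30). The log2 fold change furthest from 0, -3.62, belonged to chromosome 19 at 4449130 to 4449644 (0.501 ± 0.390 against 6.27 ± 8.11 CPM), where control replicate 3 alone had 18.4 CPM and the estimate without that library was -2.17. The remaining 4 regions had log2 fold changes of -1.97 (chromosome 5, 104416937 to 104418379), -2.06 (chromosome 8, 61444708 to 61446691), -2.16 (chromosome 11, 117493379 to 117494931) and -1.997 (chromosome 18, 70290043 to 70290487). Scaled by region totals alone, the log2 fold changes of the named regions ran from 2.03 to 3.41 on the higher side and from -2.24 to -0.945 on the lower side. There the regions of chromosome 11 at 3058579 and chromosome 18 at 70290043 both had -0.945 and that of chromosome 5 at 104416937 had -1.0.

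**Figure D2:**
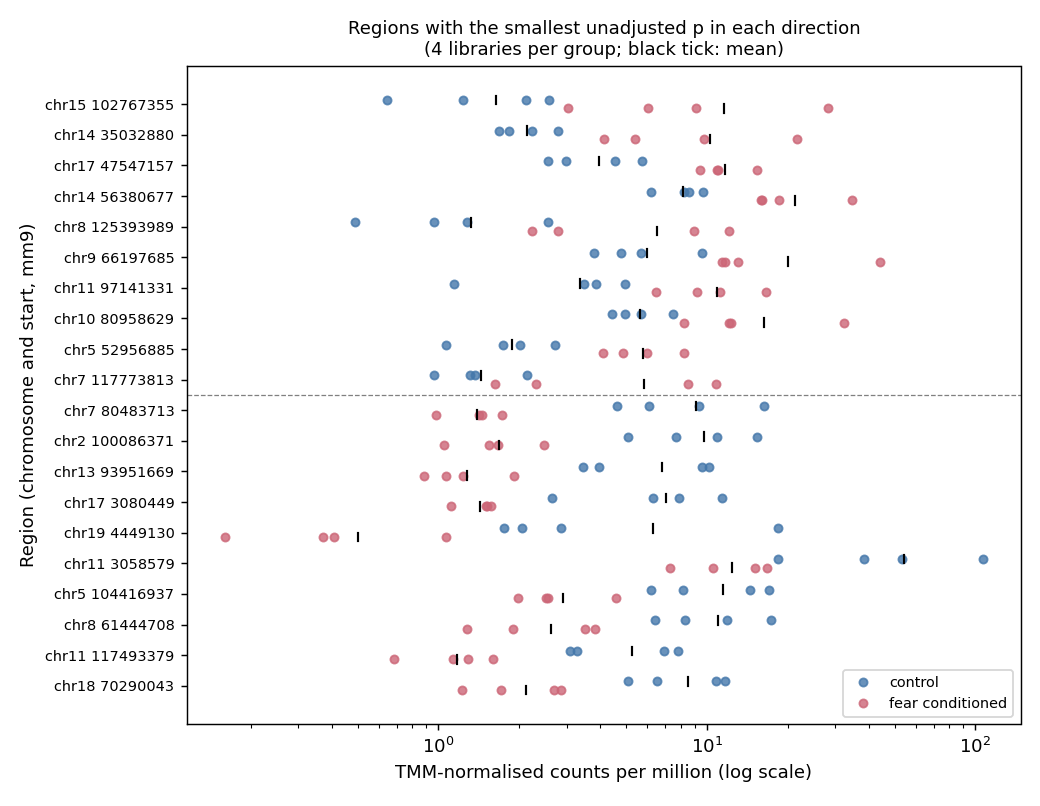
Each line is 1 region, from the 10 with the smallest unadjusted p among regions higher after conditioning (above the dashed line) and the 10 with the smallest among regions lower. Each point is the TMM-normalised CPM of 1 library on a log axis, with a black tick at the mean of the 4 libraries of a group. The groups are apart in 18 of the 20 regions, and the highest conditioned point of the upper 10 is replicate 2 in 9 of them. The 20 were picked for small p on these same libraries, so groups that lie apart follow largely from the selection. Over all regions 2.4% had groups apart, where 2.86% would be found by chance.

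Across all regions, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave 0 of 11304 regions at adjusted p below 0.05 (smallest adjusted p = 0.605). At unadjusted p below 0.05 there were 881 regions (7.79%), with 199 higher and 682 lower after conditioning. Uniform p-values would give 565, but 14 of the 35 splits of the libraries into 4 and 4, the real one included, gave at least 881. An excess over chance was therefore not shown. The comparison is a weak one, since the splits are not alike. Their median was 940 with control replicates 1 and 3 on the same side, as in the real split, and 563 otherwise. Non-overlapping groups were found in 271 regions (2.40%), where 2.86% would be found by chance; 169 of them were higher and 102 lower. The log2 fold changes had a median of -0.05, with the 5th and the 95th percentile at -1.37 and 0.82, and a median SE of 0.50. The split of unadjusted calls depended on scaling, with 277 higher and 505 lower under upper-quartile factors and 1091 higher and 39 lower with region totals alone, which moved the median log2 fold change to 0.75. DESeq2's Wald test called 40 regions (2 higher, 38 lower), 11 of them among the 20 named, and the fit on region totals called 6 (3 higher, 3 lower). The 3 lower ones and the higher one of chromosome 17 at 39979506 were among the 50 highest regions. Of the lower ones, that of chromosome 2 at 98505835 had a log2 fold change of only -0.087. In the others, on chromosome 8 at 125593958 and 128242572, control replicate 3 held 3.02% and 1.51% of its counts, more than any other library. Among fits with each of the 6 pairs of controls, chosen after seeing the data, the pair of control replicates 1 and 3 gave 148 regions (0 higher, 148 lower). The other 5 pairs gave 0. Leaving out 1 library gave no call either, with 526 unadjusted regions without conditioned replicate 2, 559 without conditioned replicate 4, and up to 1180 without control replicate 4. In simulated counts with the dispersion of these libraries, the edgeR test recovered 0% of regions changed 1.5-fold, 2% of those changed 2-fold, 26% of those changed 4-fold and 92% of those changed 8-fold (50 regions each). Differences of 4-fold or less were thus mostly not detected in the simulation. These rates hold for 200 regions changed at once, which makes the adjusted threshold easier to reach. In the real data, the region of chromosome 7 at 80483713 had an unadjusted p of 0.000121 and an adjusted p of 0.605 in edgeR. Where few regions change, changes of 8-fold may therefore also be missed, and the rates are not a detection limit of these libraries.

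The number of listed peaks differed by less than the spread between libraries. Conditioned libraries had 779690 ± 276350 and control libraries 652622 ± 204847 peaks (SD, n = 4 each), a difference of 127068 (SE 171997; exact permutation p = 0.457, two-sided; Benjamini-Hochberg value 0.686 over 9 measures). Leaving out 1 library moved this difference between 59159 without conditioned replicate 4 and 260549 without conditioned replicate 2. The covered length was 112 ± 36.0 Mb in conditioned and 97.9 ± 44.2 Mb in control libraries (SD, n = 4 each; exact permutation p = 0.686). Peaks with a z score of at least 30, the level behind the deposited number of carriers per region, were present in 10507, 6629, 10740 and 11048 of the regions in conditioned replicates 1 to 4 and in 2747, 9973, 2882 and 8385 in control replicates 1 to 4. The difference of 3734 regions (SE 2136) had an exact permutation p of 0.171 (Benjamini-Hochberg value 0.386, n = 4 each). With 4 libraries against 4, the smallest two-sided p of these tests is 0.0286.

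Peaks were also compared by overlap. With all listed peaks, 10747 of the 11304 regions held a peak in all 8 libraries, so this measure leaves little room for a difference. With it, 0 regions held a peak in every library of one group and in none of the other. When a peak had to cover 50% of the region, 41 regions were exclusive to a group (38 conditioned, 3 control; exact p = 0.114), and with peaks at z of at least 30 there were 175 (174 conditioned, 1 control; exact p = 0.143). At that z, control replicates 1 and 3 had a peak in only 24.3% and 25.5% of the regions, against 58.6% to 97.7% in the other libraries. Such low rates by themselves favour regions exclusive to the conditioned group. The mean Jaccard index of peak lists was 0.155 within and 0.159 between groups, a difference of -0.004 (exact p = 0.743, one-sided for more overlap within groups). That difference was 0.0058 without control replicate 1 (exact p = 0.143). Across regions, the log2 CPM of control replicate 1 correlated with that of the other 7 libraries at Pearson's r of 0.318 to 0.559, and the other 21 pairs of libraries at 0.564 to 0.825. Regions are not independent replicates. Pairs from the same group had a median r of 0.685 and pairs from different groups one of 0.657.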

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

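For groups of 4 values, the gap of the highest or lowest library to its neighbour was set against the group's range. Of 76 groups, 10 passed the 5% level of 0.829. Chance gives about 1 in 20 for independent normal values, whereas these values were not logged and share the same 8 libraries. The number of regions at z of at least 30 and the regions with high counts entered this test after their values had been seen, and the 4 regions given in percent of counts were picked because they varied most between libraries. The named regions were picked for small p on the same libraries, so the 10 cannot be set against chance.

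Conditioned replicate 2 stood apart from the other conditioned libraries in 5 measures besides one high-count region. It had 6629 regions with a peak at z of at least 30, against 10507 to 11048 in the other 3. Its total count was also lower, at 36857885 against 75230707 to 83233550, and an effect of depth on the number of regions was not tested. Its CPM was the highest of its group in the named regions of chromosome 14 at 56380677 (34.8 CPM), chromosome 9 at 66197685 (44.0 CPM) and chromosome 10 at 80958629 (32.4 CPM). It was the lowest of its group on chromosome 17 at 3080449 (1.11 CPM). In the region of chromosome 13 at 104995081 to 104995516 it held 0.336% of the library's counts, against 0.00208% to 0.0367% in the other conditioned libraries.

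Control replicate 3 stood apart from the other controls in 4 regions. On chromosome 19 at 4449130 it had 18.4 CPM, against 1.75 to 2.87 in the other 3 controls. A narrow region of chromosome 8 at 125593958 to 125594404 held 3.02% of its counts, or 1111841 reads, against 0.0205% to 0.0635% in the other controls. It also held 0.207% of its counts on chromosome 9 at 122178685 to 122179086 and 0.123% on chromosome 8 at 79958335 to 79958772, where the other controls had at most 0.0282% and 0.0101%.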

How the results depend on the processing

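Fits with each pair of controls, 3 factors of unwanted variation, the fit without the 50 highest regions, the z minimum of 30, the share of counts, and the runs without 1 library for exclusive regions, Jaccard index, regions at z of at least 30 and share were chosen after seeing the data. The count of 0 regions at adjusted p below 0.05 stayed at 0 in all fits except region totals alone (6 regions, 3 higher and 3 lower), DESeq2's Wald test (40 regions, 2 higher and 38 lower; adjusted p NA for 166) and control replicates 1 and 3 alone (148 regions, all lower); it was also 0 in each fit without 1 library, and the smallest adjusted p over the other fits ranged from 0.121 to 0.989. The cause was not tested beyond the splits of the libraries and the pairs of controls. At unadjusted p below 0.05, the counts ran from 472 (voom) to 1711 (control replicates 1 and 3 alone), and from 526 to 1180 without 1 library; without control replicate 1, 424 regions were higher, and without conditioned replicate 2, 85. For the 20 named regions, 18 alternative values passed the threshold (11 with DESeq2, 1 with totals alone, 6 with control replicates 1 and 3 alone). The other count filters removed no region and test nothing.

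Regions exclusive to a group went from 0 to 41 with 50% coverage and to 175 with peaks at z of at least 30, which by construction remove weak peaks. With all listed peaks nearly every region holds a peak in all 8 libraries, so the 0 there, also without 1 library, says nothing about stability. The Jaccard difference of -0.004 ranged from -0.0082 to 0.0058 without 1 library and turned positive without control replicate 1 (0.0058); the cause was not tested. The differences in peaks, in regions at z of at least 30 (2651 to 5060 without 1 library) and in share of counts (3.74 to 6.91) kept their direction, with no exact p below 0.05.

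The titles give replicates 1 to 4 the numbers 1, 4, 6 and 9 in both groups, and the labels give 4 experiment days. Whether the numbers mark shared days is not stated in the labels. Deviations from the group mean correlated between same-numbered samples at r of 0.161, 0.0482, -0.063 and 0.272. For 1 of the 4 numbers this was the best match for both of its samples. Deviations within a group of 4 depend on each other and carry the differences between libraries, so these values cannot tell whether the numbers pair the samples. A matched design therefore remains possible, and the replicate block was kept as an alternative. With the replicate block, 0 regions passed and 662 had unadjusted p below 0.05; the peak difference of 127068 had an exact sign-flip p of 0.5; 4 pairs cannot reach 0.05. Not run were a library size from another depth value, GC correction, gene lists, annotation classes, and tests on called regions, since 0 were called; autosomes alone would change nothing. The lowest median count per region of a library was 115 and the biological coefficient of variation 0.53, so spread between libraries limits the precision more than counting does.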

Other observations

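In this part, the tests of sequencing depth, of strong peaks in control replicates 1 and 3, of the share against conditioning, of the highest regions in 2 parts, of the pairs of controls, of splits with control replicates 1 and 3 together or apart, and of the splits at the adjusted threshold were chosen after their results had been seen, as was the z minimum of 30. The tests of splits at the unadjusted threshold and with DESeq2, of neighbouring regions, and of the excess in control replicates 1 and 3 were written down before their results.

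With peaks at z of at least 30, 174 regions had a peak in all 4 conditioned libraries and in no control, and 1 region had the opposite pattern. The 174 had a median log2 fold change of 0.48, 129 of them had a higher fitted value after conditioning, and 15 had an unadjusted p below 0.05 in edgeR. That level was reached by 7.79% of all 11304 regions. Peaks and counts come from the same libraries, so a higher fitted value in most of the 174 follows largely from how they were picked. Over all regions, 9151 had more conditioned carriers, 243 more control carriers and 1910 equal numbers. Control replicates 1 and 3 had a peak at this z in only 24.3% and 25.5% of the regions, against 58.6% to 97.7% in the other libraries. Such low rates by themselves favour regions with more conditioned carriers. Other splits of the 8 libraries gave up to 925 such exclusive regions, against 175 for the real one.

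At adjusted p below 0.05 in edgeR, all 35 splits of the libraries gave 0 regions, which tests nothing, since any split reaches a real count of 0. Chance was not excluded for the other 2 counts. At unadjusted p below 0.05, 14 of the 35 splits gave at least the real 881 (highest other 1704), and with DESeq2 9 of the 35 gave at least the real 40 (highest other 421). All 8 other DESeq2 splits with as many regions put control replicates 1 and 3 on the same side, and the highest count with them apart was 12, which points to a structure of the samples. Keeping them together was not enough for a high count. With conditioned replicate 4 on their side the splits gave 1 to 14 regions. With conditioned replicate 1 and not 4 on their side they gave 317 to 421. The median unadjusted count was 940 in the 15 splits that kept them together and 563 in the 20 that parted them.

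Control replicates 1 and 3 had the lowest shares of counts outside the 50 highest regions, 3.36% and 5.36%, against 9.24% to 17.6% in the other 6 libraries. Sequencing depth, taken as the total counts over the listed regions, is argued against as the only cause. A higher share and a lower total than in control replicate 1 were found in 4 libraries, among them control replicate 3. Conditioned replicate 2, at 36857885 counts against 36786183 for control replicate 3, had a share of 12.2%. These totals hold the highest regions themselves and the number of reads sequenced was not used here, so they stand in for depth only roughly. More background in control replicate 1 is a candidate explanation, since 1.45% of its own peaks reached z of 30 against at least 4.46% in the other 6 (SD 1.32). For control replicate 3 the value was 4.34%, within that SD, and this remains open. An effect of conditioning also remains open, with an exact permutation p of 0.171 for the share and a mean of 11.4% in control replicates 2 and 4 against 13.1% in the 4 conditioned libraries.

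At unadjusted p below 0.05, 682 regions were lower and 199 higher after conditioning. Over the 682, the median log2 excess above the conditioned mean was 2.29 and 1.90 in control replicates 1 and 3 and 0.57 and 0.55 in replicates 2 and 4, and the median difference between these pairs was 1.38 (SD 1.19 across regions), against -0.07 over the 199 and -0.06 over all 11304 regions. Background of control replicates 1 and 3, scaled up by small TMM factors, may account for part of the imbalance, but the 682 were picked on the same libraries, and libraries that vary more would also carry more of the excess in such a selection. With all controls 77.4% of the regions at this level were lower, against 82.3% to 85.7% in the 3 fits with a pair of controls that held control replicate 1 and 60.1% (378 higher, 569 lower, control replicates 2 and 4) to 72.5% in the 3 without it. Lower accessibility after conditioning remains open, since the 60.1% lay below the value with all controls and above 50%, while region totals alone gave 1091 higher and 39 lower regions and 169 of the 271 regions with non-overlapping groups were higher.

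Of the 50 highest regions, the 22 at the start of chromosome 9 kept nearly 1 ratio to the rest of the 50. Their shares of the counts of the 50 had a median coefficient of variation between libraries of 0.0329 and a highest of 0.0846. Regions outside the 50 had a median of 0.477, taken over shares of their own, different total. Variation that the 50 have in common cancels in the first measure, and the 22 held 31.4% of all counts on average. The values thus argue only against each of the 22 varying on its own as regions outside the 50 do. High-copy sequence whose reads pile up at few places of the assembly is a candidate explanation. This measure cannot tell it from another signal shared by the 50. The other 28 were mixed, with a median of 0.304, a lowest of 0.0194 and a highest of 2.26, and 10 of them lay above 0.477. The lowest belonged to the region of chromosome 2 at 98505835, with 37.8% of all counts on average, which in itself lowers this measure. That of chromosome 12 at 3109704, with 8.12% of counts, had 0.0239. For the 28 as a set neither explanation is settled. No genome of this build was used here to look at the sequences.

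A hypothesis that neighbouring regions move together with conditioning was tested on 3694 pairs of regions at most 50000 bp apart. Their log2 fold changes correlated at r = 0.146 across pairs, which are not independent, and 4 of the 35 splits gave as high a value (highest other 0.199). The correlation was thus no higher than chance allows. Its median was 0.129 in splits that kept control replicates 1 and 3 together and 0.042 in the others.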
